A study of Spodoptera litura with 9 samples.

How the data were processed

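RNA was taken from Spodoptera litura testes at 3 stages, with 3 libraries each. Per the labels' protocols, ribosomal RNA was depleted, strands were marked with dUTP and libraries were sequenced on a NovaSeq instrument. The deposited table holds estimated counts (expected counts) for each lncRNA transcript, not scaled to depth. Between 62% and 66% of the values of a library are whole numbers, zeros included, and the rest carry decimals. Here and below, a value is called whole, and rows identical, only where this holds exactly for the values as deposited, before rounding. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, StringTie 1.3.4 and DESeq2 1.6.3 were used, with no roles given. The counting tool, genome build, annotation and lncRNA filters are not given in the sources used here, nor is whether counting used the strand. Levels of lncRNAs that overlap another gene are therefore uncertain. The table is of transcripts, and how reads shared by transcripts of a locus were assigned is not given in the sources used here.

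Values were rounded to whole counts. The test had been planned for whole counts as deposited. All 9 columns were matched to samples by name, and 0 rows lacked a name. Library totals, the share of counts in the 10 most abundant lncRNAs and the number detected were computed first. No pair of libraries within a stage agreed within sampling noise (chi-square per degree of freedom between 16.33 and 135.19). Of the rows, 155 were at 0 throughout. Another 80 rows fell into 23 sets with identical values in all 9 libraries (42 of these rows were tested).

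Annotated IDs were looked up by accession, without the version, in a table of RefSeq genes for the assembly ASM270686v4. Of 557 IDs, 275 matched, to 260 genes (2 matched with their version). The match was to an lncRNA gene for 271 and to a protein-coding gene for 3. The assembly was used only for names and for which coding genes neighbour or overlap each other, and 230 matched IDs were placed, 73 of them overlapping a coding gene. No limit was set on the distance to a neighbour. A gene given below as beside an lncRNA was picked for having a gene name and need not be the nearest. Assembled IDs could not be named, since the files do not pair them with genes.

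The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors and filterByExpr by stage, on all 9 libraries so that the stages share 1 estimate of spread (6 residual degrees of freedom, common biological coefficient of variation 0.28). It tested 1913 lncRNAs and left out 563 with low counts. Contrasts were L6D6 against L6D4, P0D against L6D6, P0D against L6D4, any difference between stages, and the difference between the 2 successive steps. A change was called at a Benjamini-Hochberg adjusted p under 0.05. CPM are scaled to a library's lncRNA total times its TMM factor, so they are shares of the lncRNA table and not of all reads. Where a stage had no count, the fold is a lower bound against a floor of 3 counts over the 3 libraries of that stage, and no fitted fold or SE is given. These floors cover counting error only. The intervals given below for odds ratios take the lncRNAs as independent. Library totals lay between 2665564 and 4262520 counts, but the 10 most abundant lncRNAs left between 756779 and 1349182 counts per library for all others.

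On simulated counts of 1913 lncRNAs with the real depths and mean levels, 1 dispersion per lncRNA for all stages and 100 lncRNAs changed at each fold, the step into fusion recovered 39% of 2-fold and 85% of 4-fold changes, with 8 false calls (6.1% of all its calls). The step out of fusion recovered 40% and 85%, with 7 false calls (5.3% of all its calls). No recovered change had the wrong sign. Since the stages shared the simulated dispersion, this does not compare the power of the 2 steps.

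The rule for named lncRNAs was fixed before the data were examined, as were the contrasts, the alternatives not listed below as added, and the themes of the neighbour lists. In each pairwise comparison it took called lncRNAs with a mean count of at least 50 whose CPM did not overlap between the stages. Non-overlap is found by chance for 10% of unchanged lncRNAs at 3 against 3; it was found for 42.3%, 17.4% and 38.6% of tested lncRNAs. It named the 10 largest rises and 10 largest falls among IDs with a gene symbol and, read to cover the rest, the 2 largest of each among IDs without. It also named the 2 most abundant lncRNAs and the 2 with the largest excess and deficit at L6D6. Lists were planned by words in gene names; the reference gives symbols alone, so words were translated into symbols after the table's neighbours had been seen and before any list's result. Some symbols, such as Cyp18a1 and Boule, go beyond the planned words. With at most 2 tested members a list, set tests were not run.

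Composition was compared with two-sided exact permutation tests, whose smallest p is 0.1 here. The share of called lncRNAs among annotated and assembled IDs was compared with Fisher's exact test. Correlations between steps were set beside 100 simulated sets of unchanged stages. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings and filters, stricter thresholds, a replicate block, leaving out each library, and dropping the 10 most abundant lncRNAs. Chosen after seeing the data were sums over loci, rows of whole numbers only, and 1 row per set of identical rows. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.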

Results

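Long non-coding RNAs (lncRNAs) were measured by RNA sequencing in the testes of the tobacco cutworm Spodoptera litura, a moth whose paired larval testes fuse around pupation. The series asks what changes during this fusion. Testes came from sixth instar larvae aged 4 days (L6D4, before fusion), sixth instar prepupae aged 6 days (L6D6, during fusion) and pupae on day 0 (P0D, after fusion). Each stage had 3 libraries, 9 in all. Fusion goes together with age and with the passage from larva to pupa in these samples, so these cannot be told apart. The steps into and out of fusion are named so only for the order of the stages. The lncRNA table held 2476 transcripts, of which 557 carried annotated IDs and 1919 carried IDs of a transcript assembly in 1727 loci. Library totals lay between 2665564 and 4262520 lncRNA counts. The labels do not say whether the repeats were separate animals, so p-values measure the spread between these samples, which may be technical. The mRNA and miRNA parts of the series were not analysed here.

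A pair of transcripts made up about as much of each library as all others together. The assembled transcript MSTRG.17821.1 took between 28.45% and 34.67% of the counts of a library. The annotated transcript XR_002696881.1, of the gene LOC111353488, took between 17.3% and 26.54%. Neither passed the threshold over the 3 stages (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.556 and 0.331). At L6D4, L6D6 and P0D, MSTRG.17821.1 stood at 360210 ± 56220, 278193 ± 22398 and 305915 ± 101676 CPM (SD, n = 3 each). XR_002696881.1 stood at 299385 ± 51040, 218002 ± 15026 and 205623 ± 83441 CPM (SD, n = 3 each). With this spread a change is not excluded. The 10 most abundant lncRNAs held 69.98% ± 1.88 of the counts at L6D4, 66.17% ± 1.75 at L6D6 and 66.27% ± 6.4 at P0D (SD, n = 3 each). A count of 1 or more was found for 2077 ± 31.2 lncRNAs at L6D4, against 2147 ± 2.52 at L6D6 and 2148 ± 16.2 at P0D (SD, n = 3 each). Every L6D6 library had more detected lncRNAs than every L6D4 library, and with 3 against 3 the two-sided exact permutation test gave p = 0.1, the smallest it can give (adjusted p = 0.34 over 27 such tests). Thinned to the smallest library, the means were 2064 at L6D4, 2130 at L6D6 and 2124 at P0D, with the same exact p for L6D6 against L6D4. Library P0D-3 stood apart in composition, with 59.42% of its counts in its 10 most abundant lncRNAs and a TMM factor of 1.448, against 0.741 to 1.126 in the other 8 libraries.

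**Figure D1:**
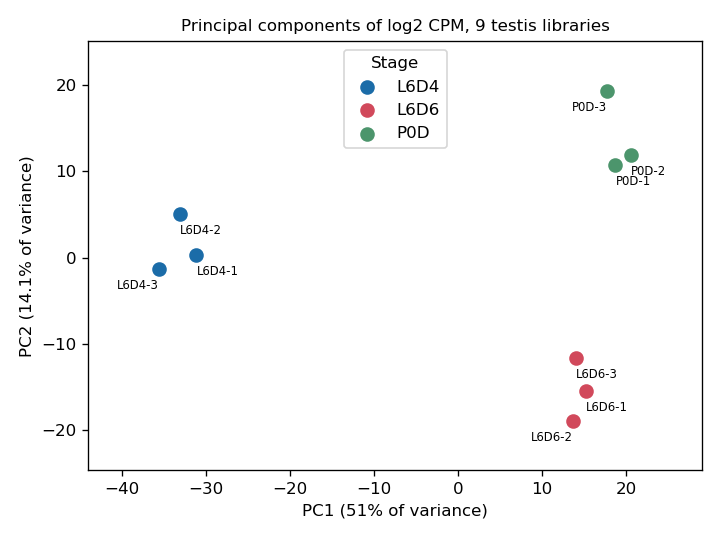
Principal components of log2 CPM over the 1913 tested lncRNAs, 1 point per library, coloured by stage, with the axes giving the share of variance of each component. The L6D4 libraries lie between -35.59 and -31.16 on the first component (51% of variance) and the other 6 between 13.65 and 20.59, while the second component (14.1%) parts L6D6 from P0D.

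The libraries separated by stage, with L6D4 farthest from the rest. Across lncRNAs, log2 CPM correlated at 0.91 to 0.944 between L6D6 and P0D libraries. It correlated at 0.866 to 0.89 between L6D4 and L6D6, and at 0.84 to 0.868 between L6D4 and P0D. Correlations within a stage lay between 0.934 and 0.968. These are correlations across genes, which are not independent replicates.

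From L6D4 to L6D6, the step into fusion, 422 of 1913 tested lncRNAs changed, 248 higher and 174 lower at L6D6. Among lncRNAs without a gene symbol and with a mean count of at least 50, the largest rises were in assembled transcripts, whose IDs the files do not pair with gene names. MSTRG.15510.1 rose from 1.34 ± 0.72 CPM to 7788 ± 499 (SD, n = 3 each), from 2, 4 and 4 counts to 29788, 30898 and 29421. MSTRG.13874.1 had no count in any L6D4 library and 314 ± 103 CPM at L6D6 (SD, n = 3), at least 862-fold higher against a floor of 3 counts over the stage. Among the same lncRNAs the largest fall was in XR_002696920.1, from 827 ± 10.6 to 51.6 ± 13.4 CPM (SD, n = 3 each; log2 fold change -4.00, SE 0.21). MSTRG.4214.1 was uneven before the step, at 163 ± 160 CPM, and stood at 12.9 ± 2.13 CPM after it (SD, n = 3 each). In edgeR's quasi-likelihood test the adjusted p of these 4 lay between 4.12e-10 and 0.00153.

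Of the 132 tested lncRNAs with a gene symbol in the reference, 35 changed in this step, 18 higher and 17 lower, with each of several identical rows counted. The 20 named here were those with the largest changes by a fixed rule; each lay wholly above or wholly below L6D4 in all 3 L6D6 libraries. LOC111360913 was represented by transcripts XR_002697178.1, which rose from 27.9 ± 11.9 to 209 ± 16.9 CPM, and XR_002697176.1, which rose from no count to 26.1 ± 4.33 CPM (SD, n = 3 each), at least 72.1-fold. The most abundant transcript of that gene, XR_002697175.1, named here after its values were seen, stood at 941 ± 150 and 1025 ± 32.1 CPM (SD, n = 3 each). The sum over the 4 transcripts of LOC111360913 had a log2 fold change of 0.42 (SE 0.16, adjusted p = 0.0798 by edgeR's quasi-likelihood test). LOC111347958, which lies beside the gene c12.2, rose from 25.7 ± 8.88 to 111 ± 30.5 CPM (SD, n = 3 each; log2 fold change 2.12, SE 0.38). Smaller rises were seen in LOC111351378, beside kin17, a nucleic acid-binding protein gene (log2 fold change 1.04, SE 0.33), and in LOC111347786, beside Bsg, the gene of the membrane glycoprotein basigin (0.83, SE 0.20). LOC111360892 rose by 0.77 (SE 0.22) and LOC111354302 by 0.85 (SE 0.25) on the log2 scale. Rises of 0.77 (SE 0.20) in LOC111352996, LOC111353338 and LOC111356537 are 1 signal: these belong to a set of 7 rows with identical values in every library, so their reads could not be told apart. Adjusted p among these rises ran from 5.11e-06 to 0.0393 (edgeR). Without L6D6 replicate 2 the calls ended for LOC111351378 (adjusted p = 0.116), LOC111354302 (0.122), LOC111360892 (0.0575), LOC111347786 (0.0502) and the identical copies (0.078), and each of these but LOC111347786 also lost its call without L6D6 replicate 1 and without 1 or both of L6D4 replicates 1 and 2 (edgeR). The same held for LOC111354302 without L6D4 replicate 3, for LOC111354302 and LOC111351378 without L6D6 replicate 3 or P0D replicate 2, and for LOC111360892 without L6D6 replicate 3.

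Among the named falls, LOC111351439 fell from 58.8 ± 9.75 to 1.42 ± 0.76 CPM (SD, n = 3 each), 41.3-fold. LOC111347957, which overlaps the coding gene LOC111347950, fell from 53.9 ± 5.74 to 3.01 ± 1.4 CPM, and LOC111350059 from 330 ± 31.1 to 40.1 ± 1.16 CPM (SD, n = 3 each). LOC111361863 fell 6.84-fold, LOC111362060 5.02-fold and LOC111351470 2.91-fold. LOC111357182, beside st4, fell 2.21-fold, LOC111364825 fell 2.07-fold and LOC111348815 fell 1.91-fold. The transcript XR_002697156.1 of LOC111360709, beside Flo1, a flotillin gene, fell 2.15-fold, while the sum over the 4 transcripts of that gene had a log2 fold change of -0.49 (SE 0.22, adjusted p = 0.134 by edgeR). Adjusted p among these falls ran from 5.88e-07 to 0.0218 (edgeR). The call for LOC111348815 ended without L6D4 replicate 1 or 3 or L6D6 replicate 1 or 3 (adjusted p between 0.0636 and 0.101), that for LOC111364825 without L6D6 replicate 2 (0.0511), and with library totals as the only scaling those for LOC111357182, LOC111360709, LOC111364825 and LOC111348815 (0.0641 to 0.175, edgeR).

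Among all 422 changed lncRNAs, 318 changed at least 2-fold, 194 higher and 124 lower, and the median size of the change was 1.51 on the log2 scale. Scaled by library totals alone, the median log2 fold of all tested lncRNAs moved to 0.314, against -0.02 with TMM, so changes are given relative to the bulk of lncRNAs. With that scaling the split was 329 higher and 78 lower. Without L6D6 replicate 1 the count was 279, and without L6D6 replicate 2 it was 272.

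**Figure D2:**
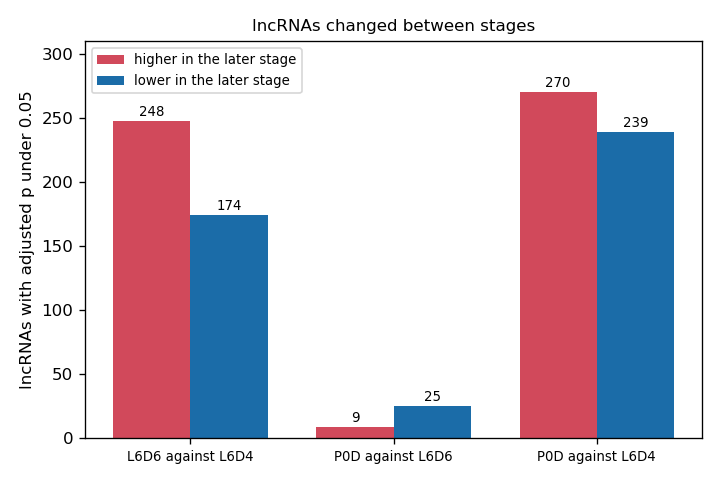
Number of lncRNAs past an adjusted p of 0.05 in each comparison, with separate bars for those higher and lower in the later stage. The bars stand at 248 and 174 from L6D4 to L6D6, 9 and 25 from L6D6 to P0D, and 270 and 239 from L6D4 to P0D.

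From L6D6 to P0D, the step out of fusion, 34 of 1913 lncRNAs changed, 9 higher and 25 lower at P0D. An unadjusted p under 0.05 was found for 223 (edgeR), against 656 in the step into fusion. A share of 0.05 of unchanged lncRNAs would fall under it by chance. MSTRG.10524.2 rose from 13.3 ± 4.71 to 660 ± 98.3 CPM (SD, n = 3 each; log2 fold change 5.62, SE 0.31), and MSTRG.14678.1 from 12.3 ± 1.59 to 97.6 ± 66.5 CPM (SD, n = 3 each). MSTRG.13874.1, high at L6D6, fell to 0.55 ± 0.73 CPM, and MSTRG.17050.1 fell from 293 ± 37.2 to 4.92 ± 2.14 CPM (SD, n = 3 each). Among lncRNAs with a gene symbol 6 changed, 2 higher and 4 lower. LOC111347958, beside c12.2, fell from 111 ± 30.5 to 4.61 ± 2.7 CPM, 23.9-fold (SD, n = 3 each). LOC111361863 fell 3.55-fold and LOC111355855 fell 2.14-fold. LOC111353724 fell 1.77-fold (log2 fold change -0.82, SE 0.17); it overlaps Snoo, a gene of the Ski/Sno family of transcriptional regulators, and lies between Sptr and ScpX. LOC111347957 rose 3.6-fold, to 10.8 ± 0.98 CPM, and LOC111350059 rose 2.42-fold, to 97.2 ± 16.9 CPM (SD, n = 3 each), both after a fall in the step before. Adjusted p lay between 6.81e-05 and 0.0289 for these 6 and between 8.76e-07 and 0.0235 for the 4 assembled transcripts (edgeR). The call for LOC111353724 ended without any library other than L6D4 replicates 2 and 3 (adjusted p between 0.0536 and 0.118), and that for MSTRG.14678.1 without any L6D6 library or P0D replicate 2 (0.105 to 0.165). Calls also ended for LOC111355855 without L6D6 replicate 3 (0.0619) or P0D replicate 2 (0.0702), for LOC111361863 without L6D6 replicate 2 (0.0561) or P0D replicate 2 (0.0646), and for LOC111347957 in a fit of the 2 stages alone (0.0558, edgeR), which also ended that for LOC111353724 (0.0528). With library totals as the only scaling the calls for LOC111347957, LOC111355855, LOC111353724 and MSTRG.14678.1 ended (0.0522 to 0.182). DESeq2 called 64 lncRNAs in this comparison, 28 higher and 36 lower, among them all 34 that edgeR called. The number higher at P0D also moved with limma-voom (19 higher, 27 lower) and without P0D replicate 1 (17 higher, 28 lower).

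**Figure D3:**
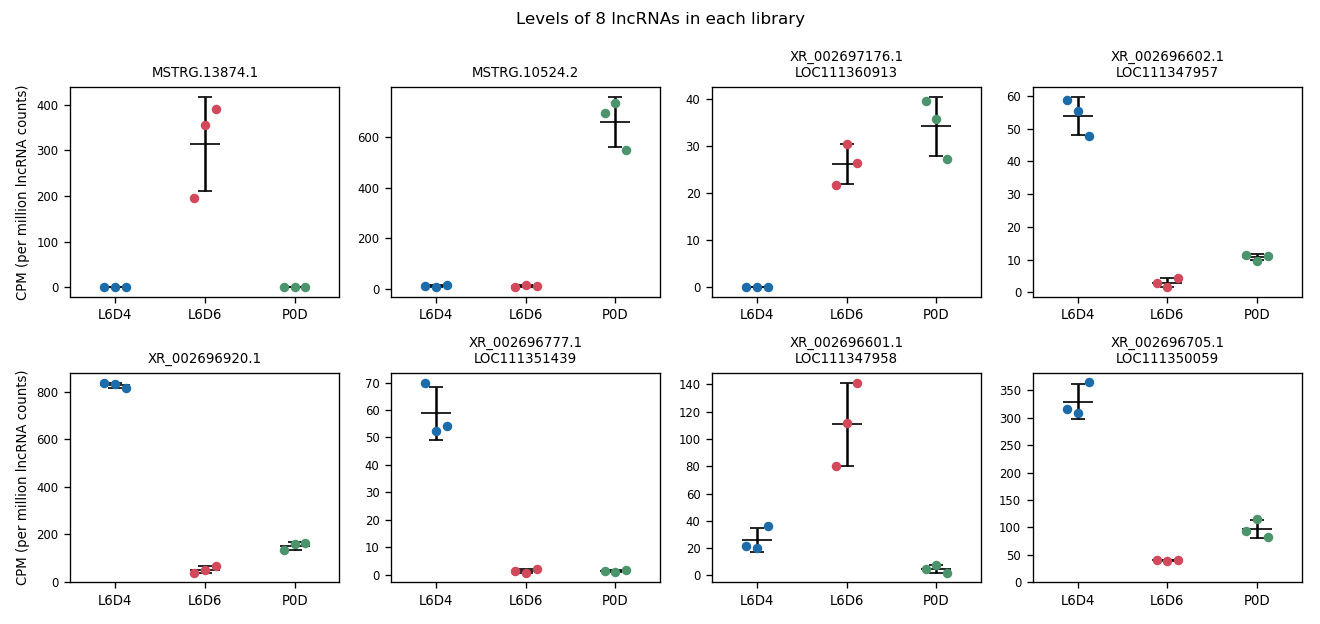
CPM (scaled to the lncRNA total of a library; linear axes that differ between panels) of 8 lncRNAs in each library, with 1 point per library, a horizontal line at the mean of a stage and error bars of 1 SD (n = 3). MSTRG.13874.1 reaches 196 to 390 CPM at L6D6 and at most 1.38 CPM in the other stages, and MSTRG.10524.2 reaches 549 to 735 CPM at P0D and at most 18.2 CPM in the other stages.

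Between the ends of the series, L6D4 and P0D, 509 of 1913 lncRNAs changed, 270 higher and 239 lower at P0D, and 372 changed at least 2-fold. Of the 4 transcripts of LOC111360913, the 2 that rose into fusion stayed up, XR_002697178.1 at 292 ± 39.4 CPM and XR_002697176.1 at 34.1 ± 6.26 CPM (SD, n = 3 each). The sum over that gene's transcripts had a log2 fold change of 0.44 (SE 0.16, adjusted p = 0.0611 by edgeR). LOC111360892 rose by 1.20 (SE 0.22) and LOC111347786, beside Bsg, by 0.96 (SE 0.20) on the log2 scale. LOC111354302 rose by 0.80 (SE 0.25). LOC111364459, beside Sec24CD, whose product belongs to the COPII coat of secretory vesicles, rose by 0.53 (SE 0.16) from 3842 ± 299 to 5554 ± 628 CPM (SD, n = 3 each). Among assembled transcripts, MSTRG.15510.1 stood at 2050 ± 387 CPM at P0D, and MSTRG.16536.1, without a count at L6D4, at 55 ± 20.3 CPM (SD, n = 3 each), at least 150-fold higher. Adjusted p of the rises with a gene symbol ran from 3.35e-06 to 0.0358, and it was 1.82e-09 for MSTRG.15510.1 and 5.17e-05 for MSTRG.16536.1 (edgeR). The call for LOC111364459 ended without L6D4 replicate 1 or 3, L6D6 replicate 2, or P0D replicate 1 or 2 (adjusted p between 0.053 and 0.103), and that for LOC111354302 without L6D4 replicate 2 or 3, L6D6 replicate 2 or 3, or P0D replicate 1 or 2 (0.0559 to 0.126, edgeR). Both ended in a fit of the 2 stages alone (0.0677 and 0.0916), and that for LOC111354302 also with DESeq2 (0.0529) and limma-voom (0.0534).

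Lower at P0D than at L6D4 were LOC111351439 (41.3-fold), LOC111361863 (24.3-fold), LOC111347958 (5.49-fold), LOC111347957 (4.99-fold) and LOC111362060 (4.52-fold). LOC111351470, LOC111350059, LOC111364825, LOC111355855 and LOC111357182 fell between 2.29-fold and 3.7-fold. Adjusted p of these 10 lay between 1.72e-06 and 0.00302 (edgeR), and with library totals as the only scaling the call for LOC111357182 ended (0.0782). In all, 31 lncRNAs with a gene symbol changed, 12 higher and 19 lower. MSTRG.8613.1 fell from 74.5 ± 38 CPM (SD, n = 3) to no count at P0D, at least 267-fold, and MSTRG.10.2 from 103 ± 21 to 5.35 ± 7 CPM (SD, n = 3 each). Both had no count in L6D6-3, beside 229 and 345 counts of MSTRG.8613.1 and 322 and 419 of MSTRG.10.2 in the other L6D6 libraries. The call for MSTRG.10.2 ended without L6D4 replicate 1 or 2 or P0D replicate 1 or 3 (adjusted p between 0.054 and 0.099, edgeR), and with limma-voom both calls ended (0.177 for MSTRG.10.2 and 0.144 for MSTRG.8613.1). For MSTRG.10.2 the call also ended with DESeq2 (0.117) and with library totals as the only scaling (0.0716). Scaled by library totals alone, the 471 changed lncRNAs split into 373 higher and 98 lower.

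The first step and the whole span called many lncRNAs in common: 193 were higher and 144 lower in both, and 4 went opposite ways. Independent lists of these sizes would share 35 and 21.74. Both comparisons use the L6D4 libraries. Simulated unchanged groups shared 0.04 calls on average in 100 draws. They held only 0.17 calls on average in the first step, so they cannot show how much sharing the common libraries cause. With 3 libraries the L6D4 group could not be split into groups of at least 2 each, so part of the excess may come from the shared libraries.

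Over the 3 stages together, 474 lncRNAs differed. By the calls of the 2 steps, 204 of them rose into fusion with no call afterwards and 156 fell with no call afterwards. Another 17 rose and then fell, and 3 fell and then rose. A call in the same direction in both steps was found for 1 rising and 2 falling lncRNAs. The second step alone was called for 5 rising and 6 falling ones, and neither step for 80. No test compared these profiles.

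Tested directly, the change into fusion differed from the change out of it for 149 lncRNAs. L6D6 lay above the mean of the other stages for 105 of them and below it for 44. Of the 149, 98 were also called higher and 41 lower in the step into fusion, but 21 lower and 5 higher in the step out of it, so the test also passes for lncRNAs that moved from L6D4 with no later call. The largest excess at L6D6 was in MSTRG.13874.1 and in MSTRG.15510.1, the latter by 7.26 on the log2 scale. For MSTRG.15510.1 most of this excess lay against L6D4, with 1.34 ± 0.72 CPM there, 7788 ± 499 at L6D6 and 2050 ± 387 at P0D (SD, n = 3 each). The largest deficits were in MSTRG.1545.3, with 19 ± 3.41 CPM at L6D4, no count at L6D6 and 0.55 ± 0.96 CPM at P0D (SD, n = 3 each), and in LOC111347957, at -3.01 on the log2 scale. The call for MSTRG.1545.3 (adjusted p = 0.0261, edgeR) ended without L6D4 replicate 1, any L6D6 library or P0D replicate 1. Without L6D6 replicate 1 the count was 84, with 73 above and 11 below, and without L6D6 replicate 2 it was 80, with 66 above and 14 below. Scaled by library totals alone it split into 122 above and 15 below.

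Across the 1913 lncRNAs, the log2 folds of the 2 steps correlated at r = -0.218 (Pearson) and -0.032 (Spearman). The steps share the L6D6 libraries with opposite sign, and simulated unchanged stages gave mean correlations of -0.491 and -0.458. The covariance was -0.256, against a simulated mean of -0.107. Real changes also alter these measures and the simulated stages held none. The simulated values therefore show only what shared libraries give without change, and are no test of the observed ones. The overlap of rises with later falls was 17 lncRNAs, where independent lists would share 3.24. Simulated unchanged stages shared 0.02 calls of any direction on average. They held only 0.17 and 0.2 calls in the 2 steps, so they cannot show what the shared libraries add to the 17. Part of this excess may come from the shared libraries, which could not be split.

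Annotated lncRNAs were called more often than assembled ones in the step out of fusion, 10 of 248 (4%) against 24 of 1665 (1.4%). The odds ratio was 2.87 (95% interval 1.21 to 6.32; two-sided Fisher's exact test, p = 0.0085, adjusted p = 0.034 over 4 comparisons). Among the most abundant of 3 equal groups of lncRNAs it was 10.07 (interval 1.92 to 66.08, adjusted p = 0.0293 over 12 tests by Fisher's exact test), resting on 5 annotated and 3 assembled calls. In the middle group it was 2.7 (interval 0.47 to 10.64, adjusted p = 0.329) and in the least abundant 1.16 (interval 0.12 to 5.57, adjusted p = 0.761, Fisher's exact test). In the step into fusion the shares were 25% and 21.6%, over the 3 stages 27.4% and 24.4%, and for P0D against L6D4 23.8% and 27%, the annotated share being the lower there (Fisher's exact test, adjusted p = 0.317 for each). Genes are not independent replicates, and sets of identical rows were all counted.

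Neighbouring genes were grouped into 7 lists. From the adhesion list, LOC111348367 changed. It has the cadherin gene Cad86C as a neighbour, which is not the coding gene nearest to it. It rose from 0.22 ± 0.19 CPM at L6D4 to 4.29 ± 2.18 at L6D6 and 12.4 ± 2.33 at P0D (SD, n = 3 each). Its log2 fold change was 3.97 (SE 0.78) into fusion and 5.49 (SE 0.73) over the whole span, from 1, 1 and 0 counts at L6D4. It was the only tested member of the adhesion list, of 3, so its p adjusted over the list alone is its unadjusted p, 0.00753 in the step out of fusion by edgeR, where it did not pass over all lncRNAs (adjusted p = 0.182). Among all tested lncRNAs 22.1% changed into fusion and 26.6% over the whole span, so 1 changed member does not set the adhesion list apart. Of the cytoskeleton list 1 of 5 members was tested, LOC111351410 beside Arp1, with a log2 fold change of -0.93 (SE 0.33) over the whole span (adjusted p = 0.0561 over all lncRNAs by edgeR, not past the threshold; adjusted over the list alone, which is the unadjusted p here, 0.0155). The sum over the 2 transcripts of LOC111351410 passed, at -0.90 (SE 0.30, adjusted p = 0.0416 by edgeR). Of genes typical of other tissues, such as cuticle and fat body, 2 of 6 members were tested and none changed over all lncRNAs. LOC111355499, beside the cuticle gene CPG13, stood at 6.24 ± 2.61, 7.55 ± 2.07 and 2.77 ± 0.67 CPM at L6D4, L6D6 and P0D (SD, n = 3 each), with an adjusted p of 0.204 for the step out of fusion over all lncRNAs and 0.02 adjusted over the list alone (edgeR). LOC111348453, beside Lzm, belongs to a set of 13 identical rows and stood at 51.7 ± 18.8, 63.3 ± 13.5 and 64.4 ± 20.8 CPM (SD, n = 3 each). No member was tested in the lists of hormone genes (2 members), sperm and axoneme (1), and cell cycle and meiosis (1), and the list of proteolysis and cell death had 0 members.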

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

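The tests of explanations below were set before their results were seen, except that of the 3 pairs of transcripts called in opposite directions, which was added afterwards. The comparison of effect sizes was first run on lncRNAs with a mean count of at least 50, which departed from that plan, and then on all tested lncRNAs with a count in every stage.

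The changes into and out of fusion differed for 149 lncRNAs, by a test of the difference itself. Of 100 splits of the 9 libraries, the real one included, 3 gave as many calls, and the highest other split gave 474. These splits shuffle all stages at once, while L6D4 stood apart from the other stages. They therefore cannot test whether the changes into and out of fusion differ, and chance is not excluded by them for this contrast. The splits with more calls point to a structure of the samples. The one with 474 compared the intact L6D4 group with mixtures of L6D6 and P0D libraries, and the other, with 266, kept the true stages with P0D as the middle one.

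From L6D4 to L6D6 422 lncRNAs changed, and from L6D6 to P0D 34. With an unadjusted p under 0.05 (edgeR) there were 656 and 223, a smaller gap. A wider spread of the P0D libraries could hide changes of the second step, but the mean squared log2 fold beyond its squared standard error was 1.196 in the first step and 0.285 in the second. Their ratio was at most 0.263 in the fit of all libraries and the 9 fits leaving out each in turn, and at most 0.286 for a mean count of at least 50. The stages share 1 estimate of spread, so part of the gap in calls may still come from the P0D libraries. Differing depth and the scaling factors are argued against too: with the counts outside the 10 most abundant lncRNAs thinned to 756779 per library, the first step had at least 10.65 times the calls of the second in 10 thinnings, and under 4 other scalings at least 12.14 times (with rows of whole numbers only, 249 calls against 48). The stage of the testes, the time between samplings and the origin of the repeats stay open and were not tested as reasons.

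In 10 of 1285 lncRNAs with a mean count of at least 50, a library stood at 0 beside replicates of its stage at 50 or more. All 10 (100%) hold fractional values, against 54.2% of the other 1275 (Fisher's exact test, two-sided, p = 0.00263; lower 95% bound of the odds ratio 1.88). Reads assigned among overlapping transcripts may account for these zeros. Of the 10, 3 were called in a comparison, MSTRG.8613.1 and MSTRG.10.2 among them. No biological explanation was tested.

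Transcripts of 1 assembled locus were called in opposite directions in 3 pairs, each from L6D4 to P0D: MSTRG.4110.1 and MSTRG.4110.2 (log2 folds -0.75 and 3.52), MSTRG.10487.1 and MSTRG.10487.2 (-0.81 and 2.45), and MSTRG.2786.1 and MSTRG.2786.2 (3.30 and -4.53). Reads traded between them are a candidate explanation, which would make their deviations within a stage run against each other. The correlations of these deviations were 0.309, -0.4 and -0.533, and their median of -0.4 lies within the range of as many random pairs matched on mean count (-0.583 to 0.594), so 3 pairs are too few to decide. Over 100 pairs of transcripts with a mean count of at least 50 each, in 78 loci, the median was 0.363 (random -0.122 to 0.169) and 11 pairs lay below -0.5 (random 10 to 26), but that set is wider than the 3 pairs and excludes nothing for them. The sum over the locus changed from L6D4 to P0D for MSTRG.2786 (log2 fold 1.42, adjusted p = 0.0178 by edgeR). It did not pass for MSTRG.4110 (log2 fold 0.03) or MSTRG.10487 (log2 fold 0.30, adjusted p = 0.334 by edgeR).

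The splits of the libraries in pairwise comparisons number 10, too few for a share under 0.05. L6D6 against L6D4 gave 422 calls and the highest other split gave 1. P0D against L6D6 gave 34 and the highest other 0, and P0D against L6D4 gave 509 and the highest other 1. Over the 3 stages, 1 of 100 splits, the real one, gave as many as 474 calls. The highest other gave 356 and kept the L6D4 group intact. The splits therefore argue only against a random grouping of all 9 libraries. They cannot show that L6D6 and P0D differ, since L6D4 alone stood apart from the rest.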

How the results depend on the processing

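Sums over loci, rows of whole numbers only and 1 row per set of identical rows were chosen after seeing the data. Of 1278 values computed for 60 named results, none reversed, 1155 kept their side of the threshold and 123 were no longer past it, most often with glmTreat (25). Most named results were chosen for large called changes in these same libraries, so the lack of reversals says little. Not every alternative gave each named result a value: rows of whole numbers gave 36 and sums over loci 1, and the sums over LOC111360913 and LOC111360709, which did not pass, are not among the 123. Counts of calls stayed within 1.5 times under the other scalings, filters, limma-voom, sums over loci and identical rows. The lncRNAs called were not always the same ones. For L6D6 against L6D4, DESeq2 size factors kept 419 of the 422 calls, upper-quartile factors 405 and library totals alone 318. Library totals alone kept 27 of 34 calls for P0D against L6D6 and 368 of 509 for P0D against L6D4. For the difference between steps they kept 108 of 149. DESeq2 called 64 lncRNAs for P0D against L6D6; the cause was not tested. Testing against a log2 fold of 1 (glmTreat), a stricter question, left 148 for L6D6 against L6D4, 20 for P0D against L6D6 and 185 for P0D against L6D4. Rows of whole numbers only left 972 to test, with 249 for L6D6 against L6D4, 48 for P0D against L6D6 (21 higher and 27 lower, 22 of the 34 kept), 296 for P0D against L6D4 and 295 over the stages.

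Leaving out each library gave 272 to 509 lncRNAs for L6D6 against L6D4, 26 to 45 for P0D against L6D6, 363 to 479 for P0D against L6D4, 354 to 514 over the stages and 80 to 169 for the difference between steps. With at least 10 counts in 6 libraries the correlation between steps was -0.135; the cause was not tested. With only the nearest gene, 0 neighbour-list members were called into fusion, since Cad86C is not the nearest to its lncRNA. Set tests with an estimated correlation were not run.

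Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.154 and 0.089. With the replicate block the counts were 376, 29 and 442 for the pairwise comparisons in the order above, 409 over the stages and 141 for the difference between steps, and 9 of the 60 named results were no longer past the threshold (adjusted p between 0.0501 and 0.101, edgeR). The counts left outside the dominant transcripts limit what low lncRNAs can show.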

Other observations

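Some lncRNAs were found in whole stages and in no library of another. With no count in any L6D4 library, 7 lncRNAs had at least 10 counts in every L6D6 library and 6 in every P0D library. In the other direction, 1 lncRNA with at least 10 counts in every L6D4 library had none at L6D6 and 1 had none at P0D. Between L6D6 and P0D, 0 lncRNAs met this rule either way. The difference between these numbers was not tested.

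Within the gene LOC111360913, which had 4 transcripts, XR_002697178.1 and XR_002697176.1 rose beside another that passed no test between stages. XR_002697176.1 had no count at L6D4, 26.1 ± 4.33 CPM at L6D6 and 34.1 ± 6.26 CPM at P0D (SD, n = 3 each). The transcript XR_002697178.1 stood at 27.9 ± 11.9, 209 ± 16.9 and 292 ± 39.4 CPM at L6D4, L6D6 and P0D, beside 941 ± 150, 1025 ± 32.1 and 932 ± 214 CPM for XR_002697175.1 (SD, n = 3 each). The sum over the gene stood at 1001 ± 91, 1342 ± 99.8 and 1360.5 ± 223 CPM (SD, n = 3 each). How reads shared between its transcripts were assigned is not given in the sources used here, and whether the makeup itself differed was not tested.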
